A study of soil metagenome and Rhodococcus jostii RHA1
Sphingomonas sp. NM05
Bordetella sp. IITR-02 and Escherichia coli K-12
Rhodococcus jostii RHA1
Sphingomonas sp. NM05
Escherichia coli BL21
Escherichia coli DH5[alpha]
Bordetella sp. IITR-02 with 17 samples.

How the data were processed

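Genomic DNA of 17 samples had been cut with AluI and RsaI, labelled with Cy3 and hybridised to a custom Agilent array, per the labels. The deposited scanner files hold, per the file headers, intensity values of each spot, namely the processed signal after background subtraction and detrending within the array, the mean spot signal and the median local background, with no normalization between arrays. The deposited files also hold other values, per the file headers flags of 0 or 1 for a spot well above background, positive and significant, saturated or not uniform. The deposited series table holds intensity values that equal the processed signal of each array within rounding. The files were written by Agilent Feature Extraction, version 9.5.1.1 for the site slide and 10.5.1.1 for the other slides by their headers, whereas the labels name 9.5.1.1 for the pure-culture slide too.

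Spots were grouped into 1372 genes by the gene name and identifier that the files give, with 8296 distinct probe sequences and a median of 8 probes per gene. Of the genes, 276 had a probe sequence shared with another gene. Forms of the same gene could be entered under several names or identifiers, so counts of genes are counts of entries and not of independent loci. No reference came with the series, and gene names and descriptions are those of the files. Replicate spots were averaged and a gene's value was the median of its probes. Values were log2 processed signals minus the 75th percentile of the array, taken over all non-control probes on the site slide, where most spots were well above background on all arrays, and over the probes well above background on every array of the slide elsewhere, which were 51 on the pure-culture slide and 3263 on the mixture slide. On the site slide, where some signals were 0 or less, values were held at a floor set at 0.203 of the detection limit. Genes with no probe well above background on any array of a comparison were left out of its test, as were genes with a missing value or without residual variance. Array quality is given as the share of spots well above background, and intensities allow no counting interval.

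Comparisons were made with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, 1 fit per slide, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Groups with 1 array were assumed to vary like the others. On the pure-culture and mixture slides the software gave spots that were not positive and significant a surrogate value, constant within every array but array 1. For this reason a call was counted as meeting the detection criteria only if the gene was well above background on every array of the brighter group and that group's mean lay above the detection limit of the other. A fold given as at least a value was computed against that limit with and without scaling, and the lesser of the 2 is printed. Gene lists were tested with camera at a preset correlation of 0.01 and with an estimated one. Of the lists, 27 were fixed before the data were examined, and 4 were added after the annotation was read and before any comparison was computed. The fixed Enterobacteria list found 0 genes on the array and the Bordetella list 2, so that neither the E. coli strains nor IITR-02 could be followed by a list. Comparisons of single arrays had no test. Their list medians were ranked among 10000 random lists matched on mean signal. The genes of a random list were drawn independently, so the percentiles take no account of correlation between the genes of a list and are not p values. Strain shares were taken from the labels and tested by exact permutation. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

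Named genes were the 10 with the largest difference each way among those past the threshold and well above background on every array of the higher group, up to 3 per list, and all lin genes. For single arrays the difference had to be at least 2 on the log2 scale. The groups, comparisons, tests, this rule and most alternatives were fixed before the data were examined. The 18 genes bright on DH5alpha were chosen afterwards, by a difference of 4 on the log2 scale from NM-05, as were the detection criteria, which were added after the first counts had been seen.

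The fits were first run with a floor at the detection limit on all slides, which had not been planned. It tied so many values that 685 genes on the mixture slide, 924 on the pure-culture slide and 93 on the site slide had no residual variance, and calls then arose from rounding. After its counts had been seen, that version was replaced by the planned values without this floor, and it is kept as an alternative in which genes without residual variance are left out.

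The fits were tested on simulated data with tied undetected spots. Changes were given only to genes whose mean lay above the detection limit of every array of the slide. For arrays labelled degraders only against array 5, run on 834 genes, 46.0% of changes of 1, 86.0% of changes of 2, 88.0% of changes of 4 and 96.0% of changes of 6 on the log2 scale were recovered, and 26 of 184 calls were false, of which 1 met the detection criteria. For IPL soil against NM-05, run on 661 genes, 372 of 420 calls were false, of which 1 met the detection criteria, which is why the counts meeting these criteria are given for every comparison. For the contaminated sites against the river, run on 1179 genes, 6.00% of changes of 1, 52.0% of changes of 2, 70.0% of changes of 4 and 60.0% of changes of 6 were recovered.

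Alternatives were the other choice of probes for the scaling percentile, no scaling, median centring, quantile normalization, normexp background correction with an offset of 50, the series table, probes in place of genes, other filters on dim genes, the array row as a block, limma with a trend and robust variance, and leaving out each array in turn. Added after the data were seen were floors, a correction for probe GC content by a loess curve with a span of 0.5, the mixture arrays without those at odds with their labels, and no scaling for single-array results.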

Results

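Genomic DNA from soils, sludges, a river sediment, pure cultures and defined mixtures of bacteria was hybridised in 1 colour to an array of 60-base probes for biodegradation genes and bacterial 16S rRNA genes. The 17 arrays lay on 3 slides, and each array carried 15207 non-control spots that were grouped into 1372 genes, of which 114 were 16S rRNA genes. The site slide held 1 array each for a chloroaromatic-contaminated soil and sludge, a river sediment, a CETP sludge, a heavy metal-contaminated soil and sludge, and a petroleum sludge. The pure-culture slide held Sphingomonas sp. NM-05, a degrader of the pesticide gamma-hexachlorocyclohexane (HCH), Escherichia coli DH5alpha, and 2 aliquots of soil DNA from around the pesticide factory IPL. The mixture slide held 8 arrays, numbered here 1 to 8 by their labels. Arrays 1 to 3 were labelled as 3 degraders (NM-05, Bordetella sp. IITR-02 and Rhodococcus jostii RHA1) plus 3 E. coli non-degraders, arrays 4, 6, 7 and 8 as degraders only, and array 5 as non-degraders only. By the labels, array 1 was a mixed culture in equal ratio and array 2 had 2 parts of degraders to 1 of non-degraders. Array 3 was instead DNA isolated from each strain separately and mixed in equal ratio. Array 4 held the degraders in equal ratio, and arrays 6, 7 and 8 had NM-05, IITR-02 and RHA1 doubled, respectively. The arrays of a group were thus not replicates of the same mixture, and the errors of the mixture comparisons include these differences. The source text of array 5 named E. coli non-degraders alone, but its organism field also listed Sphingomonas sp. NM05.

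The share of spots well above background lay between 79.0% and 84.0% on the site slide, and between 30.0% and 55.9% on the mixture slide. It was 37.2% for NM-05, 9.15% for DH5alpha, and only 3.07% and 2.54% for the IPL soil aliquots. The number of genes with at least 1 probe well above background was 1198 to 1260 at the 5 sites, 773 to 1057 on the mixture arrays, 803 for NM-05, 459 for DH5alpha, and 262 and 221 for the IPL soil aliquots. The small number of arrays per group limits the precision of every comparison below.

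The pure cultures served as the positive and the negative control, with 1 array each and no test. Among the 10 genes with the largest difference toward NM-05, 8 were lin genes, which encode the HCH degradation pathway. Some of them were forms of the same gene, such as LinD_DQ401108 and linD2_DQ480725. LinD_DQ401108 (a 2,5-dichlorohydroquinone reductive dechlorinase) was at least 369-fold brighter on NM-05 and linB_AY331259 (a halidohydrolase) at least 154-fold. The other 2 were pcpA_AF512952 (a dichlorohydroquinone dioxygenase), at least 116-fold, and the Alcaligenes 16S rRNA gene AY753188, at least 113-fold brighter on NM-05. In the other direction, ycdM_UTI89_C1075 (a putative monooxygenase) was at least 612-fold and the alkanesulfonate monooxygenase NT12EC0968 at least 531-fold brighter on DH5alpha. By a difference of at least 2 on the log2 scale, 165 genes were higher and 70 lower on NM-05, and 409 and 24 without scaling.

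The comparison of arrays labelled degraders only (n = 4) with the array labelled non-degraders only (n = 1) asked which genes carry signal from the degraders over E. coli alone. The lin genes stood far above the E. coli array. LinD_DQ401108 was higher by 9.77 ± 0.39 (log2, SE), at least 511-fold, with an adjusted p of 5.71e-06, and the HCH dehydrochlorinase gene linA_AY690622 was at least 138-fold higher. Of the 12 genes in the HCH list, 11 were higher, and 11 adjusted over the list alone. With the numbered forms added, 17 of 18 lin genes were higher, with a median of 8.18, or 6.68 with each gene held at its bound against the detection limit. linX_NC_006349 did not pass (-0.25).

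Sphingomonad 16S rRNA genes rose with the lin genes: 20 of 21 were higher, and 20 adjusted over the list alone (19 met the detection criteria), with a median of 5.75, or 3.45 at their bounds. X72722 of S. paucimobilis was at least 75.9-fold and AB042233 of S. herbicidovorans at least 45.7-fold higher. Of 9 Burkholderia and Ralstonia 16S rRNA genes, 8 were higher, and 8 adjusted over the list alone. These genes were bright on the NM-05 pure culture too (median of IPL soil minus NM-05 -7.17), so they do not report those genera alone. In the list of chlorobenzene and chlorocatechol genes, 26 of 83 were higher and 23 lower, against 28 and 24 adjusted over the list alone. Among those higher were the chloromuconate cycloisomerase gene tfdD_AY078159 (8.19 ± 0.41) and the maleylacetate reductase gene tcbF_M57629, at least 117-fold. The chlorobenzene dioxygenase gene tcbAa_U15298 was higher by 5.87 ± 0.57, the biphenyl dioxygenase gene bphA1_D32142 at least 28.6-fold, and the dienelactone hydrolase gene clcD_AF161263 at least 139-fold.

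No list of Rhodococcus genes rose as a whole. Of the 9 Rhodococcus 16S rRNA genes 2 were higher, among them DQ269450 of R. opacus, at least 5.17-fold, and 7 were lower, among them U16312 of strain RHA1 (-2.23 ± 0.35). These 16S rRNA genes were also bright on array 5 and on DH5alpha, both labelled as E. coli, so their signal does not follow RHA1 alone. Of the 10 genes with an RHA1 locus identifier, 0 were higher and 4 lower, of which 3 met the detection criteria. Lower genes with the largest differences were the organosulfonate monooxygenase gene ssuD_PP_0238 (-3.75 ± 0.80), the arsenic resistance gene arsB_AJ271973 (-3.48 ± 1.06) and the muconolactone isomerase gene catC_PSEEN3137 (-3.19 ± 0.54). Of the 22 Pseudomonas 16S rRNA genes 8 were lower.

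In limma, 138 genes passed as higher and 332 as lower among 1155 tested, and 134 and 296 of these were well above background on every array of the brighter group and beyond the detection limit of the other. The scaling lowered the median of all tested genes, which was -0.72 with and 0.26 without it, and without scaling 133 genes were called higher and 0 lower. Of the 34 named lower genes 33 kept their direction without it, but their differences shrank and their errors grew (median SE 0.33 with and 0.64 without scaling). ssuD_PP_0238 was then at -2.77 ± 1.11 (adjusted p = 0.240), arsB_AJ271973 at -2.50 ± 1.32 (adjusted p = 0.459) and catC_PSEEN3137 at -2.21 ± 0.89 (adjusted p = 0.244). Camera called 6 lists, namely both lin lists, the sphingomonad, Burkholderia and Ralstonia, 16S rRNA, and chlorobenzene and chlorocatechol lists. None held with an estimated correlation, where the smallest adjusted p was 0.303. The 16S rRNA list had a median of -0.10 and the chlorobenzene list one of -0.50, while their means (1.20 and 1.60) and tests pointed upward.

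A set of 18 genes that were at least 16-fold brighter on DH5alpha than on NM-05, chosen after the data were seen, was read on each mixture array as a check of its content. Several of the 18 carry the same description, such as the alkanesulfonate monooxygenases NT12EC0968, ycbN_AAN42563.1, ECs1018 and NT11EC0961, so they are not 18 independent genes. The median log2 signal of the set was 11.45 on array 5. It was 9.54, 9.67 and 10.24 on arrays 6, 7 and 8, labelled without E. coli, and all 18 genes were well above background on each. It was 1.93 on array 4, labelled without E. coli, where 6 were detected. Among arrays labelled with E. coli it was 10.16 on array 1 and 8.87 on array 2, but 2.47 on array 3, where 12 of the 18 were detected at this low level. Array 3 was the array of separately isolated DNA. By signal, 4 of the arrays labelled with degraders (3, 6, 7 and 8) were thus at odds with their labels, and by detection 3 of them were (6, 7 and 8). The lin genes had medians between 10.99 and 11.79 on all 7 arrays labelled with degraders, against 2.57 on array 5. Without arrays 3, 6, 7 and 8, array 4 alone was set against array 5 alone, with 1 residual degree of freedom from arrays 1 and 2. The fit then called 129 genes higher and 87 lower, counts that rest on the spread of another group.

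**Figure D1:**
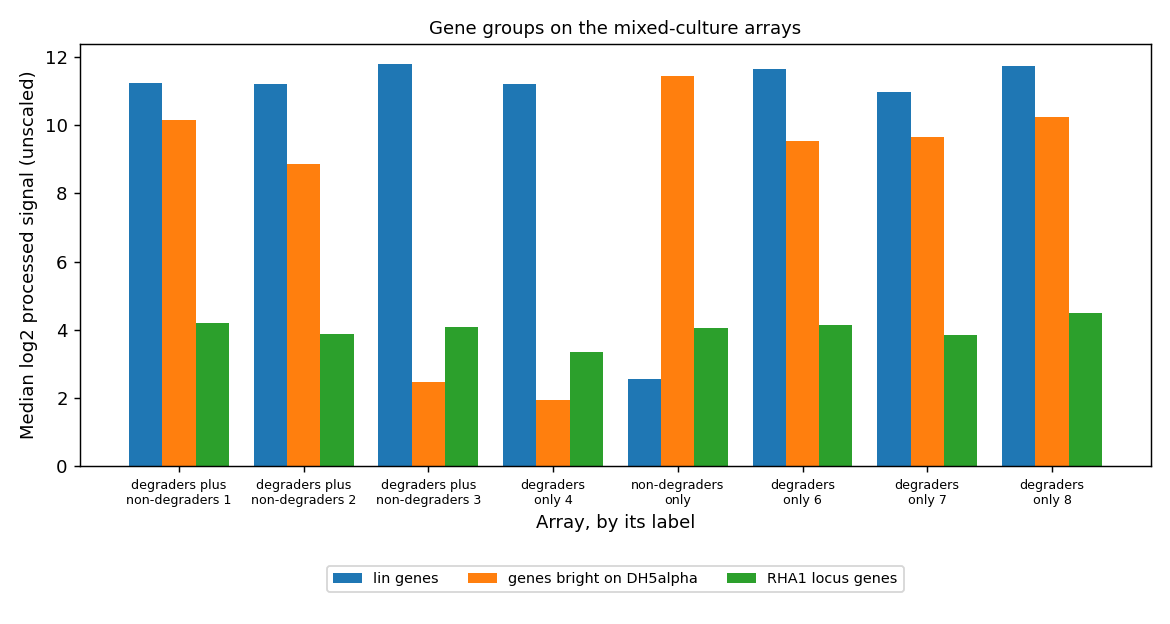
Median log2 processed signal without scaling (vertical axis) of 18 lin genes, 18 genes bright on E. coli DH5alpha, and 10 genes with RHA1 locus identifiers on each of the 8 mixture arrays (horizontal axis, by label), each bar being 1 median on 1 array. The lin bars stand between 10.99 and 11.79 on the 7 arrays labelled with degraders, the bars for genes bright on DH5alpha stand at 2.47 on array 3 and 1.93 on array 4, and the RHA1 bars lie between 3.35 and 4.50 everywhere.

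Arrays labelled degraders plus non-degraders (n = 3) were compared with the same E. coli array to ask which genes stay above it when the degraders are diluted. LinD_DQ401108 was higher by 9.76 ± 0.40, at least 509-fold, with an adjusted p of 7.02e-06, and linA_AY690622 was at least 148-fold higher. Of the HCH list 11 of 12 genes were higher, and 11 adjusted over the list alone, and with the numbered forms 17 of 18 were, with a median of 7.93, or 6.46 at their bounds. Of 22 sphingomonad 16S rRNA genes 20 were higher, and 20 adjusted over the list alone (19 met the detection criteria), with a median of 5.46. The chlorocatechol dioxygenase gene tfdCII_AY078159 (7.84 ± 0.33) and bphA1_D32142, at least 35.3-fold, were higher too. Of the 10 RHA1 locus genes 0 were higher and 5 lower.

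In limma, 136 genes were higher and 323 lower among 1164 tested, of which 133 and 298 also met the detection criteria, and without scaling these were 138 and 0, while 30 of the 34 named lower genes kept their direction. The median of all tested genes was -0.74 with and 0.46 without scaling. Camera called the same 6 lists, none of them with an estimated correlation (smallest adjusted p = 0.320). The genes bright on DH5alpha were dim on array 3 of this group, as given above, and 129 genes were called higher and 294 lower without the 4 arrays at odds with their labels, with 1 residual degree of freedom.

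Arrays labelled degraders plus non-degraders (n = 3) and degraders only (n = 4) were compared to ask what dilution with E. coli does to the signal. The lin genes differed by a median of -0.07, with 0 of 18 past the threshold. The sphingomonad 16S rRNA genes differed by 0.05 (0 of 22), the Rhodococcus ones by 0.11 (0 of 9), and the chlorobenzene and chlorocatechol genes by -0.05 (0 of 87). The 18 genes bright on DH5alpha, which arrays labelled with E. coli should carry, differed by -0.90, with 0 past the threshold. The limma fit called 0 of 1216 genes at an adjusted p under 0.05, and 6 had an unadjusted p under 0.05. With the array row as a block, limma again called 0 genes, but 318 had an unadjusted p under 0.05. All arrays labelled degraders plus non-degraders lay in the same row of the slide as array 4. Arrays 6, 7 and 8 lay in the other row. Row and label could thus be told apart only through array 4, and the absence of calls does not show that the groups were alike. In simulated data of this comparison, 66.0% of changes of 1 on the log2 scale and 94.0% of changes of 2 were recovered. These rates hold for genes with a mean above the detection limit of every array, and dimmer genes were not covered. Without the 4 arrays at odds with their labels, arrays 1 and 2 against array 4 alone gave 34 genes higher and 1 lower with 1 residual degree of freedom, but those arrays were left out for the same E. coli genes that such a comparison measures.

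Doubling of 1 strain among the degraders was read on 1 array each, without a test. The percentiles given take no account of correlation between the genes of a list. On array 6, labelled with NM-05 doubled, the sphingomonad 16S rRNA genes were 0.36 above the mean of the other degrader-only arrays, at percentile 99.5 of random gene lists of like signal, and the lin genes 0.03 above it, at percentile 85.0. On array 8, labelled with RHA1 doubled, the Rhodococcus 16S rRNA genes differed by -0.40 (percentile 13.1) and the RHA1 locus genes by -0.16 (percentile 66.5). Without scaling the differences on array 6 were 0.75 for the sphingomonad (percentile 99.4) and 0.42 for the lin genes (percentile 84.5). On array 8 they were 0.58 for the Rhodococcus (percentile 14.1) and 0.82 for the RHA1 locus genes (percentile 67.0), so neither list stood out from random lists there. Over the 8 mixtures, the labelled share of NM-05 and the signal of sphingomonad 16S rRNA genes had a Pearson r of 0.67 (exact permutation p = 0.172, adjusted 0.229) and a Spearman rho of 0.40 (exact permutation p = 0.329, adjusted 0.329), both two-sided. Without scaling the r was 0.64 and the rho 0.096 (exact permutation p = 0.827). The scaled r was 0.14 without array 5 and 0.07 without the pair of arrays farthest from the median share. It was 0.74 without array 3 (exact permutation p = 0.0778), where the rho was 0.76 (exact permutation p = 0.0571), and 0.84 without array 6 (exact permutation p = 0.0683). The share of RHA1 and the signal of Rhodococcus 16S rRNA genes had an r of -0.79 (exact permutation p = 0.0268, adjusted 0.107) and a rho of -0.67 (exact permutation p = 0.0738, adjusted 0.148). This r was -0.47 without scaling and -0.50 without the pair of arrays farthest from the median share, and these 4 tests formed 1 family. The Rhodococcus 16S rRNA genes were also bright on array 5 and on DH5alpha, both labelled as E. coli. Neither their correlation nor their difference on array 8 can therefore be read as a measure of RHA1. The labels of arrays 3, 6, 7 and 8, from which the shares were taken, were those at odds with the E. coli genes.

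The 4 contaminated sites were compared as a group with the river sediment (n = 1) to ask which genes stood above or below the river in their mean. A call does not show that each site differed from the river. The lin genes were far lower at the contaminated sites. The difference was -9.17 ± 0.28 for linA_AY690622, at least 478-fold, with an adjusted p of 6.86e-04, and -7.11 ± 0.29 for the reductive dechlorinase gene linD_AY150583. The haloalkane dehalogenase gene linB_AY903216 differed by -5.67 ± 0.32. Of the HCH list 11 of 12 genes were lower, and 11 adjusted over the list alone, and with the numbered forms 17 of 18 were, with a median of -5.69. Of the 90 chlorobenzene and chlorocatechol genes 9 were lower, and 16 adjusted over the list alone, and of the 29 chlorophenol genes 6 were, and 6 adjusted over the list alone. Among them and other genes for chlorinated aromatics were clcD_AF161263 (-5.51 ± 0.29), the dichlorohydroquinone dioxygenase gene pcpA_AF512952 (-4.99 ± 0.30), the chloromaleylacetate reductase gene PcpE_AF512952 (-4.89 ± 0.44) and tfdD_AY078159 (-3.84 ± 0.25). The alkane monooxygenase gene alkB_AJ245436 was at least 2.56-fold lower.

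Sphingomonad 16S rRNA genes had a median difference of -2.01, with 0 of 23 past the threshold, and Burkholderia and Ralstonia ones one of -3.59 (0 of 9). In limma, 0 genes were higher and 29 lower among 1271 tested, and 87 had an unadjusted p under 0.05. Camera called 9 lists, of which the lin list and its extended form held with an estimated correlation (adjusted p = 0.0156 for both). The others, among them the sphingomonad list (adjusted p = 0.952 with an estimated correlation), did not. The chlorobenzene and chlorocatechol list had a positive median (0.11), while its mean (-0.52) and its test pointed downward, as they did for the chlorophenol list (0.16 and -1.03) and for alkane hydroxylation (0.23 and -0.30). The median of 1295 genes was 0.27 with and -0.50 without scaling, and 35 genes were lower without it. The river is a single array that was assumed to vary like the other 4, and the differences hold for this sample, not for river sediments in general.

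**Figure D2:**
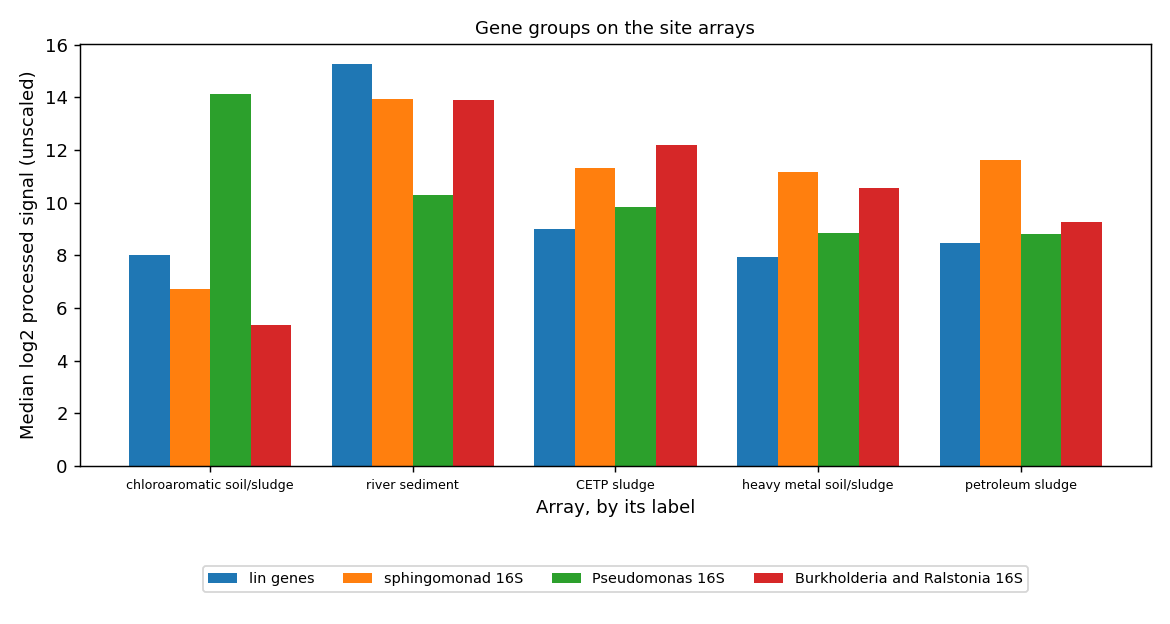
Median log2 processed signal without scaling (vertical axis) of 18 lin genes and of 23 sphingomonad, 24 Pseudomonas, and 9 Burkholderia and Ralstonia 16S rRNA genes on the 5 site arrays (horizontal axis), each bar being 1 median on 1 array. The lin bar stands at 15.25 for the river sediment and between 7.92 and 8.99 for the other sites, and the sphingomonad bar at 6.72 is lowest for the chloroaromatic site.

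Each site was then described against the mean of the other 4, without a test, and with percentiles that take no account of correlation between the genes of a list. At the chloroaromatic site, Pseudomonas 16S rRNA genes were 4.83 higher (percentile 100 of random lists), and genes of naphthalene and catechol degradation led the array. The catechol 2,3-dioxygenase gene c23o_AY228547 was at least 440-fold, the dihydroxynaphthalene dioxygenase gene nahC_J04994 at least 158-fold and the oxygenase gene doxB_M60405 at least 152-fold higher there. Burkholderia and Ralstonia (-5.55) and sphingomonad (-3.93) 16S rRNA genes were lower. On the river array, sphingomonad (2.01) and Burkholderia and Ralstonia (3.59) 16S rRNA genes stood high beside the lin genes. The river was not alone in this. Sphingomonad genes were also higher at the heavy metal (0.96) and petroleum (0.81) sites, but not in the CETP sludge (-0.05). Burkholderia and Ralstonia genes were higher in the CETP sludge (1.56) and at the heavy metal site (1.17), but not at the petroleum site (-0.91). All these differences were taken against means that include the low chloroaromatic array. The Burkholderia and Ralstonia genes were bright on the NM-05 pure culture too (median of IPL soil minus NM-05 -7.17), so they do not report those genera alone.

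The CETP sludge had high signal for the alcohol dehydrogenase gene adhC1_NE0907, at least 28.0-fold, and for 16S rRNA genes of Sedimentibacter saalensis (AJ404680), at least 16.9-fold, and Delftia tsuruhatensis (AY899912), at least 8.64-fold. At the heavy metal site the metal resistance genes differed by 0.20 as a list, where the median of all genes was 0.16 (percentile 99.2). Without scaling this list lay below the other sites (-0.47, all genes -0.66), and with median centring it differed by 0.05. The mercuric reductase gene merA_AJ418055 was 2.42 higher there with and 1.58 without scaling, and AJ404680 was at least 9.72-fold higher. At the petroleum site the genes of dibenzothiophene desulfurisation, which removes sulfur from fuel compounds, were 0.49 higher at percentile 99.8, and 0.31 higher without scaling. The benzoate dioxygenase gene benB_AJ564846 was at least 5.09-fold, the phenol hydroxylase gene mphN_AJ564846 at least 2.12-fold and the 16S rRNA gene DQ110881 of Gordonia sp. at least 10.3-fold higher there.

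IPL soil (n = 2 aliquots) was compared with DH5alpha to set soil DNA against the negative control of the same slide. The chloroaromatic site array, with 79.1% of its spots well above background against 3.07% and 2.54% for the aliquots, is labelled as from IPL too. Whether the hybridisation of the aliquots had failed was not tested, and every lower value in the soil below depends on it. The genes that were bright on DH5alpha were lower in the soil. The monooxygenase gene ycdM_UTI89_C1075 was at least 587-fold, the alkanesulfonate monooxygenase gene NT12EC0968 at least 509-fold and the chromate reductase gene chrR_DQ989184 at least 154-fold lower. All 7 Rhodococcus 16S rRNA genes tested were lower, and 7 adjusted over the list alone, with a median of -7.11, or -5.01 at their bounds. U16312 of strain RHA1 was at least 60.5-fold lower. No lin gene was called higher in the soil, where the HCH list had a median difference of 0.24 with 0 of 5 genes called, and linX2_DQ486136 was lower by at least 2.06-fold. In limma, 116 of 624 genes tested passed, 11 of them as higher, and 0 higher and 60 lower genes met the detection criteria. An unadjusted p under 0.05 was found for 232. Camera called the 16S rRNA and Rhodococcus lists, neither with an estimated correlation (adjusted p = 0.813 for both). The only residual degree of freedom is the difference between aliquots of 1 soil DNA, so that the p values cover technical error alone and not variation between soils or cultures.

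IPL soil was compared with NM-05 as the positive control. All 16 lin genes tested were lower in the soil, with a median of -8.40, or -7.07 at their bounds. LinD_DQ401108 was at least 357-fold and the maleylacetate reductase gene linF2_DQ399710 at least 207-fold lower. Of 18 sphingomonad 16S rRNA genes 15 were lower, and 15 adjusted over the list alone, all of which met the detection criteria, whereas 0 of the 2 that passed as higher did, and of 9 Burkholderia and Ralstonia ones 8 were lower. The isocitrate dehydrogenase gene Icd_TTE0387, the isopropylbenzene dioxygenase gene ipbAb_AF006691 (3.06 with and 0.83 without scaling) and the toluene o-xylene monooxygenase gene tou_AY621080 (2.96 and 0.73) were higher in the soil. No fold is given for them, since without scaling none lay above the detection limit of NM-05. In limma, 324 genes were higher and 363 lower among 925 tested, and 84 and 229 met the detection criteria. The median of all tested genes was -0.02 with and -2.25 without scaling, and without scaling 0 higher and 547 lower genes met the detection criteria. Of the 20 named higher genes 12 kept their direction without it, among them Icd_TTE0387 (3.32 ± 0.10 with and 1.09 ± 0.28 without scaling), and 8 turned. Camera called 7 lists, none with an estimated correlation (adjusted p = 0.882 for the lin list). These p values too cover technical error between aliquots alone, and the weak signal of the soil arrays applies to every lower gene.

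The labels give the IPL aliquots as a test of replication. Of the 262 and 221 genes detected, 139 were detected in both aliquots. Over these genes the Spearman rho was 0.87 and the SD of the log2 difference 0.33. Over all 1372 genes the rho was 0.80. These correlations run across genes, which are not independent replicates.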

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

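Apart from the level of the genes bright on DH5alpha on arrays labelled degraders only, for which the prediction was written before the values were seen, the tests of this part were chosen after the results were seen, and how each was read was revised after its value was known.

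Array 4 stood apart from arrays 6, 7 and 8, also labelled degraders only, in 3 of the 30 gene sets tested for a sample far from the others, where chance gives about 1 in 20. Its genes bright on DH5alpha were lowest (gap over range 0.920), and its chlorobenzene and chlorocatechol genes (0.863) and dehalogenation genes (0.877) highest. These were scaled values. On array 4 the medians of the chlorobenzene and chlorocatechol (-2.70) and dehalogenation (-3.36) genes lay under its detection limit of -2.18. That they were highest therefore does not show more signal from these genes.

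No gene differed between arrays labelled degraders plus non-degraders and degraders only, while genes bright on DH5alpha were bright on 3 arrays labelled without E. coli and dim on 1 labelled with it. For cross-hybridisation of degrader DNA, these genes lay 9.51 below array 5 (-9.51) on array 4, where lin genes were bright, and more than 2 below it on 3 such arrays. This met the prediction for its absence. The genes had been picked as dim on NM-05, however, so the outcome for NM-05 DNA was fixed in advance. Bright lin genes show NM-05 DNA alone, and RHA1 and IITR-02 DNA on array 4 was not shown by any list. The test therefore cannot decide on cross-hybridisation of DNA from those strains. E. coli DNA on the degrader-only arrays may account for the absence of differences, but the written prediction did not say how the 4 arrays were to be summarised: the median of their differences from array 5 was -1.84 and the median over all genes and arrays pooled -1.94, both within the bound of 2, and the mean was -3.60, beyond it. The arrays lay between -9.51 and -1.21, and this explanation was left undecided. Mislabelled or mixed-up samples stay open too, as 3 arrays were at odds with their labels by detection, all of them labelled without E. coli, whereas array 3 still detected 12 of 18 genes, more than the prediction allowed. The real split of the arrays called 0 genes and the highest of the others 0, so that all 35 of 35 gave as many by construction and chance was not tested, nor was any biological explanation.

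The lin genes were high on the river sediment array alone among the sites. The GC content of the probes is argued against, as the list's difference stayed at -5.59 after a correction, and so is the scaling, since it was -6.50 without any. A mislabelled sample or NM-05 DNA on this array stays open: of the 157 genes at least 16-fold brighter on NM-05 than on DH5alpha, 80.9% were brightest on the river array (78.7% without lin genes), against 32.7% of all other genes. The 16S rRNA gene DQ231244 of Sphingomonas sp. NM05 was at least 35.3-fold brighter on the river array than the mean of the other sites. EF435010 of another Sphingomonas strain was at least 75.4-fold brighter there, so these values do not single out NM-05. A river sediment rich in sphingomonads could give the same values, and with 1 array of it this was not tested.

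None of the RHA1 locus genes passed as higher on arrays labelled with degraders than on array 5. Their unscaled medians on the mixture arrays lay near the detection limits, where small differences are hard to read. Probes that bind no DNA are argued against, as 10 of the 10 genes were well above background on all 5 site arrays, though so were most other genes, which makes this test weak. Poor lysis of RHA1 cells in mixed cultures could not be decided: the array of separately isolated DNA differed by 0.023 from the mean of the other arrays labelled with degraders, but it is 1 array and its own label is in doubt. Too little RHA1 DNA in the mixtures stays open and was not tested.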

How the results depend on the processing

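No paired analysis was possible because the arrays of different groups were not matched and their replicate numbers are only names. The floors, the GC correction, the omission of arrays at odds with their labels, the unscaled values of single-array results and the omission of the pair of arrays with the farthest shares were chosen after the data were seen. Weak signal over background limits the IPL soil and DH5alpha arrays most. The causes of the changes below were not tested, except that probes outnumber genes and stricter filters or floors leave fewer genes to test.

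For arrays labelled degraders only against non-degraders only, the count of higher genes (134) stayed within 1.5 times under all alternatives except probes in place of genes (640). The count of lower genes (296) was 146 with the other scaling probes, 0 without scaling and with the series table, 52 with median centring, 44 with normexp, 1063 with probes, 87 without the arrays at odds with their labels (array 4 alone against array 5 alone), and 196 to 421 when 1 array was left out, the lowest without array 6. For degraders plus non-degraders against non-degraders only, higher genes (133) moved only with probes (636). Lower genes (298) were 125 with the other scaling probes, 0 without scaling and with the series table, 47 with median centring, 46 with normexp, 1016 with probes, 198 with the floor at the detection limit, and 174 to 395 when 1 array was left out, the lowest without array 2. For degraders plus non-degraders against degraders only, the counts were 0 under all alternatives except without the arrays at odds with their labels (34 higher, 1 lower). With the array row as a block, 318 genes had an unadjusted p under 0.05 in limma, against 6 in the main fit.

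For IPL soil against DH5alpha, higher genes (0) were 1 with the other scaling probes, 30 with quantile normalization, 16 with probes and 3 with the floor, and lower genes (60) were 431 with normexp, 17 with the stricter filter on dim genes, 287 with probes and 4 with the floor. For IPL soil against NM-05, higher genes (84) were 0 without scaling and with the series table, 44 with quantile normalization and 5 with the floor, and lower genes (229) were 547 without scaling and with the series table, 43 with the stricter filter on dim genes, 1102 with probes and 3 with the floor. Without 1 aliquot no residual degree of freedom was left and no count could be had. For the contaminated sites against the river, lower genes (29) moved only with probes (150), and were 21 to 41 when 1 site was left out.

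With an estimated correlation, camera called 0 lists in place of 6, 6, 2 and 7 for the first pair of mixture comparisons and the IPL soil comparisons, and 2 in place of 9 for the sites. The correlation of the RHA1 share (-0.79) was -0.47 without scaling, -0.50 without the pair of farthest shares and -0.88 to -0.62 when 1 array was left out. It missed the unadjusted threshold without scaling, without the pair of farthest shares, and without array 4 (-0.77) or array 5 (-0.62). The doubled RHA1 difference was 0.58 for Rhodococcus 16S rRNA genes (percentile 14.1) and 0.82 for RHA1 locus genes (percentile 67.0) without scaling. By the flag for positive and significant spots, detected genes were 1316 on NM-05, 1268 on DH5alpha, 1275 and 1260 on the IPL soil aliquots, 1310 on array 4 and 1304 on array 5.

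Of the named genes, those that turned direction did so as follows. Without scaling, and with the series table, bdsB_AB076745 was 0.017 for degraders only against non-degraders only, and for degraders plus non-degraders against non-degraders only DszC_DQ062154 was 0.31, macA_RHA1_ro11309 0.053, NC_002977_2 0.27 and ssuD1_RHA1_ro07050 0.053. For IPL soil against NM-05, also without scaling and with the series table, BD242845 was -0.40, bdsB_AB076745 -1.31, dszA_AY678116 -0.34, M29593 -0.42, nbzA_AF319591 -0.026, pnrB_AF532912 -0.97, RHA1_ro06679 -1.10 and RHA1_ro07109 -1.31, and with normexp bphC2_AB271916 was 0.013 and dszC_DQ448815 0.14. For IPL soil against DH5alpha with normexp, bphA2_D88020 was -0.058, bphC8_AB272984 -0.068, ipbAb_AF006691 -0.067, linB_DQ767899 -0.091, LinD_DQ401108 -0.10, linE_AY334273 -0.088, linF_AB177985 -0.11, poxF_NT01RE0388 -0.071 and prdA_AB194706 -0.065. For the contaminated sites against the river, no named gene turned direction under any alternative run.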

Other observations

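Rhodococcus 16S rRNA genes were bright beyond the arrays labelled with Rhodococcus. Their median log2 signal was 10.23 on array 5 and 7.42 on DH5alpha, both labelled as E. coli, and 5.70 on NM-05, against 7.86 to 10.08 on the arrays labelled with RHA1. At the sites it lay between 13.82 for the heavy metal site and 15.24 for the chloroaromatic site.

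Signal rose with the GC content of the probes on most arrays. Across the non-control spots, the Spearman rho was 0.72 to 0.79 at the sites, 0.50 to 0.59 on the mixture arrays, 0.54 on NM-05 and 0.14 on DH5alpha, and it was -0.04 and -0.08 on the IPL soil aliquots.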
